A study of Mus musculus with 10 samples.

How the data were processed

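RNA of CD4+ splenocytes was measured on Affymetrix mouse expression arrays, 1 array per mouse, in 5 mice after cecal ligation and puncture and 5 after sham surgery. Per the labels' protocols, spleens were taken 6 h after surgery under halothane, cells were enriched by immunomagnetic negative selection, RNA was extracted on columns, and biotin-labelled cRNA was made from small samples with 2 rounds of amplification, which shortens the copies towards the 3 prime end. The source labels give an individual mouse for each array, and the series names 5 biological replicates per group, so p-values are read as the spread between mice. The titles number the CLP arrays as biological replicates 1 to 5, but give replicate 1 for every sham array and tell these apart only by a suffix from 1 to 5, which is used here as the sham replicate number. The values deposited by the authors are linear intensities, 1 per probe set and array. The software, background correction and scaling behind these intensities are not given in the sources used here. Array medians differed by 11.6%, 29 values were exactly 0 and none were missing.

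The table held 45101 probe sets, 64 of them controls. Genes were named from a platform annotation table: 34945 probe sets had 1 gene symbol, 932 had several and 9160 were unnamed here. Symbols were looked up by Entrez identifier in a RefSeq gene table of assembly GRCm38.p6, where 204 named probe sets had no match and no symbol changed. No coordinates are given, since no build is named for the values.

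The steps were fixed before the data were examined, except where stated. Each array was scaled to a common median, values below the 25th percentile of all scaled values (70.4) were set to that floor, and log2 was taken. Control probe sets and those with a mean log2 below the 40th percentile were left out, which left 27022 probe sets, of which 0.132% of values lay at the floor. Groups were compared with limma 3.58.1 in R 4.3.3 (linear model, moderated variance), and p-values were adjusted by Benjamini-Hochberg over all 27022 probe sets, with a threshold of 0.05. A gene was represented by its brightest tested probe set with 1 symbol, which gave 13073 genes. Fold changes are CLP over sham, and SE is limma's moderated standard error.

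The genes named were, among those past the threshold whose 5 CLP arrays all lay above or all below the sham arrays, the 12 largest rises and the 12 largest falls by log2 fold change, leaving out clone-like and predicted names; up to 4 members with the lowest p of every fixed list; and a few sort markers. Genes named outside this rule (1500011B03Rik, Tsc22d3, Malat1, Ccr2, Itga4, Slamf6, Cd53, Rora, Rps24, Cd3g, Cflar, Traf1, Per1, Rsad2, Cxcr3 and others of lists that passed when adjusted over the list alone) were chosen after their values were seen. There were 33 fixed lists, 23 of pathways and 10 of cell types, with 481 of their 570 genes tested. Several lists share members. Lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and fry beside it, adjusted over all lists. The estimate was 0.315 for the type I interferon list, 0.317 for interferon gamma, 0.184 for glucocorticoid and 0.242 for T cell receptor and identity. Where the estimate lies above the preset, the p-value at the preset can be too small. With an estimated correlation no list passed; fry passed 1 list for a one-directional change, dendritic cells, and 15 lists for changes in either direction. List means per array and array measures were compared by exact two-sided permutation tests over 252 arrangements. Figures were drawn with matplotlib 3.10.9.

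The split of the arrays by 18S ribosomal RNA signal, at an intensity of 1000, was found after the data were seen. It was added as a block and by fitting each class alone, and the unscaled values were added as well. Other alternatives were quantile normalization, centring, filters, floors, variance models, array weights, a minimum fold of 1.2, averaging of probe sets, a block by replicate number, marker and 3 prime bias covariates, and leaving out each array. The fit was tested on simulated arrays with the means and spread of these samples, in which 200 probe sets were changed and 27022 tested for CLP against sham. The glycolysis list was shifted as well, as a check of the list test. The fit recovered 57.1% of those changed 1.5-fold, 82.0% of those changed 2-fold and 96.7% of those changed 3-fold, and 4.38% of its calls were of probe sets left unchanged. The simulated noise was independent between probe sets and held no 18S classes, so these rates may not carry over to the real arrays.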

Results

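The samples were CD4+ splenocytes of C57Bl/6 mice aged 8 to 12 weeks, taken 6 h after surgery. In 5 mice the cecum was ligated and punctured (CLP), which lets gut bacteria into the peritoneum and is a standard model of polymicrobial sepsis. In 5 sham mice the abdomen was opened without that injury. Cells were enriched by magnetic removal of the other cells, to about 91% CD4+ per the labels, and the RNA of each mouse was read on its own Affymetrix array, so n = 5 mice in each group. The deposited intensities ran from 0 to 20290, with array medians between 127.6 and 142.4. The number of arrays limits the precision of every value given here.

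The comparison asks how the transcripts of CD4+ T cells differ early in abdominal sepsis from those after surgery alone. In CLP mice 26 genes rose and 72 fell among 13073 genes tested. The rises included Il10, the anti-inflammatory cytokine, by 2.33-fold from a level near background, and Gzmb, the cytotoxic protease granzyme B, by 2.47-fold. They also included Tnfrsf9 (4-1BB), a costimulatory receptor of activated T cells, by 1.92-fold, and the glucocorticoid-inducible genes Klf9 and Dusp1, by 2.04-fold and 1.95-fold. The falls included Cd48, a ligand of the CD2 and CD244 receptors, which was 2.57-fold lower, and Rasgrp1, which links the T cell receptor to Ras, at 1.95-fold lower. Tbx21 (T-bet), the master regulator of T helper 1 cells, was 1.90-fold lower.

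Among the genes that rose with no overlap between the groups, the largest changes were those of P2ry14, a receptor for UDP-sugars (log2 fold change 1.51 ± 0.29, SE, adjusted p = 0.0455 by limma), Frmd4b (1.37 ± 0.16, adjusted p = 0.0159) and Tgm2, a transglutaminase (1.33 ± 0.19, adjusted p = 0.0205). Gzmb went from a log2 signal of 8.85 ± 0.11 (SD, n = 5) in sham arrays to 10.15 ± 0.53 in CLP arrays. Il10 went from 6.57 ± 0.18, close to the floor of 6.14, to 7.79 ± 0.52, and its log2 fold change of 1.22 was 1.06 with a floor at the 40th percentile, so its fold is less certain. The other rises of this group were Mxd1, a partner of Max that opposes Myc, Rras2, Rapgef3, a cAMP-activated exchange factor, and Phlpp1, a phosphatase of Akt, between 1.90-fold and 2.31-fold. One clone-named transcript (1500011B03Rik) rose further, by 2.90-fold, and is outside the set of named genes; its other probe set went the opposite way.

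Among the genes that fell with no overlap, Cd48 went from 9.67 ± 0.14 (SD, n = 5) in sham to 8.32 ± 0.54 in CLP arrays. Mex3b, an RNA-binding protein, was 2.44-fold lower and Tnik, a kinase of the Wnt pathway, 2.40-fold lower. Tnfsf11 (RANKL), a TNF-family cytokine made by T cells, was 2.03-fold lower, and Hsd11b1, the enzyme that regenerates active glucocorticoid, 2.02-fold lower. Rasgrp1 had a log2 fold change of -0.96 ± 0.11 (SE, adjusted p = 0.0155 by limma). Tmem154, Mcoln3, Lypd6b, Dynll1, Zmat1 and Mapre2 were between 1.92-fold and 2.13-fold lower. The CLP mean of Mcoln3, 6.66, lay close to the floor of 6.14, so its fold is less certain. Probe sets of one gene did not always move together: the other probe set of Rasgrp1 and that of Rras2 went the opposite way, and with all probe sets of a gene averaged Mxd1 (0.48), Rras2 (0.46), Tnik (-0.40) and Mapre2 (-0.32) no longer passed. Averaging also reduced Tgm2 to 0.73, Klf9 to 0.64 and Rasgrp1 to -0.47, which still passed.

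**Figure D1:**
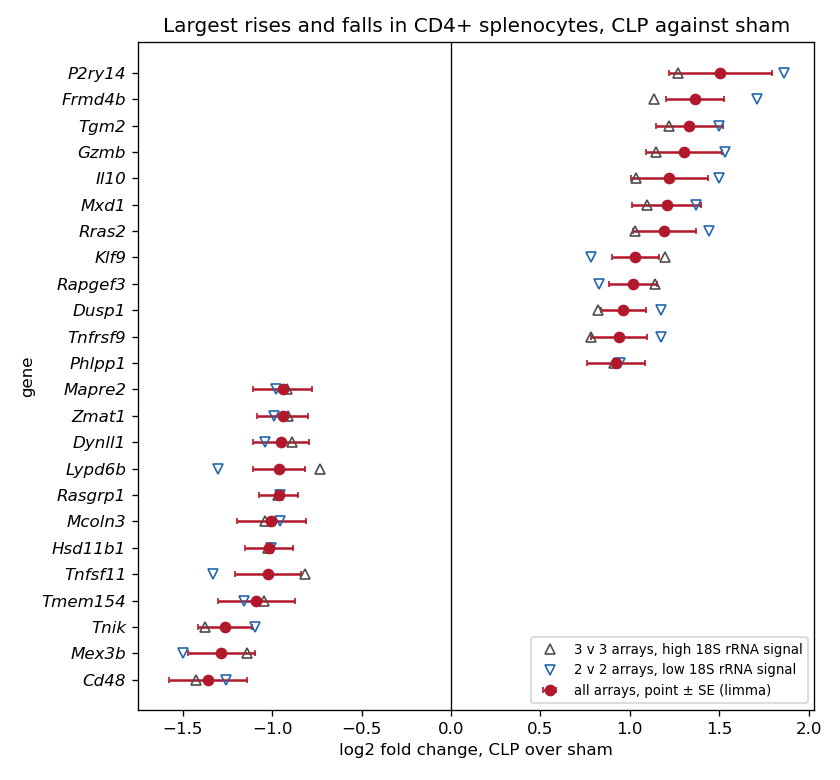
Log2 fold change (CLP over sham, x axis) of the 12 largest rises and 12 largest falls (y axis); filled circles give the estimate from all 10 arrays with its SE, open triangles the difference within the arrays of high (3 against 3) and of low (2 against 2) 18S rRNA signal.

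Among all genes tested, the 5 CLP arrays lay above every sham array in 111 (0.849%) and below every sham array in 298 (2.28%), where chance gives 0.794% for both directions together. The groups were separated in this way in 24 of the 26 genes that rose and 71 of the 72 that fell, which follows largely from their choice by the group difference. The counts moved with single arrays. Leaving out sham replicate 3 left 0 that rose and 2 that fell by limma (1170 genes at an unadjusted p under 0.05). They became 69 and 179 without CLP replicate 1, 6 and 8 without CLP replicate 2, 8 and 7 without CLP replicate 3, 3 and 4 without CLP replicate 5, 6 and 12 without sham replicate 1, 4 and 10 without sham replicate 2, 4 and 6 without sham replicate 4, and 20 and 16 without sham replicate 5.

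Interferon-induced genes were higher in CLP mice as a group. All 24 measured members of the type I interferon list had a higher mean in CLP arrays, with a median log2 fold change of 0.35 (camera adjusted p = 9.38e-13; adjusted p = 0.407 with an estimated correlation). Of these, 2 rose over all genes tested, Ifit3, an antiviral protein (1.76-fold), and Rtp4 (1.76-fold), and 10 rose when adjusted over the list alone. The latter included Oasl1 (log2 fold change 0.54 ± 0.11), Ifih1 (MDA5, a sensor of double-stranded RNA; 0.64 ± 0.14) and Rsad2 (viperin; 1.08 ± 0.29). With the 18S rRNA class of the arrays as a block, Oasl1 and Ifih1 passed over all genes tested (adjusted p = 0.0272 and 0.0383). Over 27 other settings, this block among them, Oasl1 passed in 7 and Ifih1 in 4. Of the interferon gamma list, all 17 measured members were higher on average (median 0.11, camera adjusted p = 8.98e-05; adjusted p = 0.407 with an estimated correlation). Iigp1, an interferon-inducible GTPase, rose 2.04-fold, and 3 members, with Irgm1 and Igtp, passed when adjusted over the list alone.

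The glucocorticoid-response list was also higher, with a median log2 fold change of 0.35 over 19 members (camera adjusted p = 4.78e-06; adjusted p = 0.407 with an estimated correlation). Klf9 and Dusp1 rose over all genes tested. Adjusted over the list alone, 5 members rose, among them Fkbp5, a co-chaperone of the glucocorticoid receptor (0.76 ± 0.16), Mt1 (0.82 ± 0.24) and the clock gene Per1 (0.89 ± 0.27), and Tle3 fell (-0.38 ± 0.10, and -0.16 with its probe sets averaged). Over 27 other settings the smallest values of Fkbp5 and Mt1 were both 0.50. With the 18S rRNA class as a block Fkbp5 passed over all genes tested (adjusted p = 0.0322), and it passed in 6 of those 27 settings. Tsc22d3 (GILZ) had a value of 0.27 ± 0.37 that did not pass. The oxidative stress and heme list shares Mt1 and Mt2 with it; that list had a median of 0.06 (camera adjusted p = 0.0356; adjusted p = 0.407 with an estimated correlation) and none of its 13 measured members passed over all genes tested or when adjusted over the list alone.

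**Figure D2:**
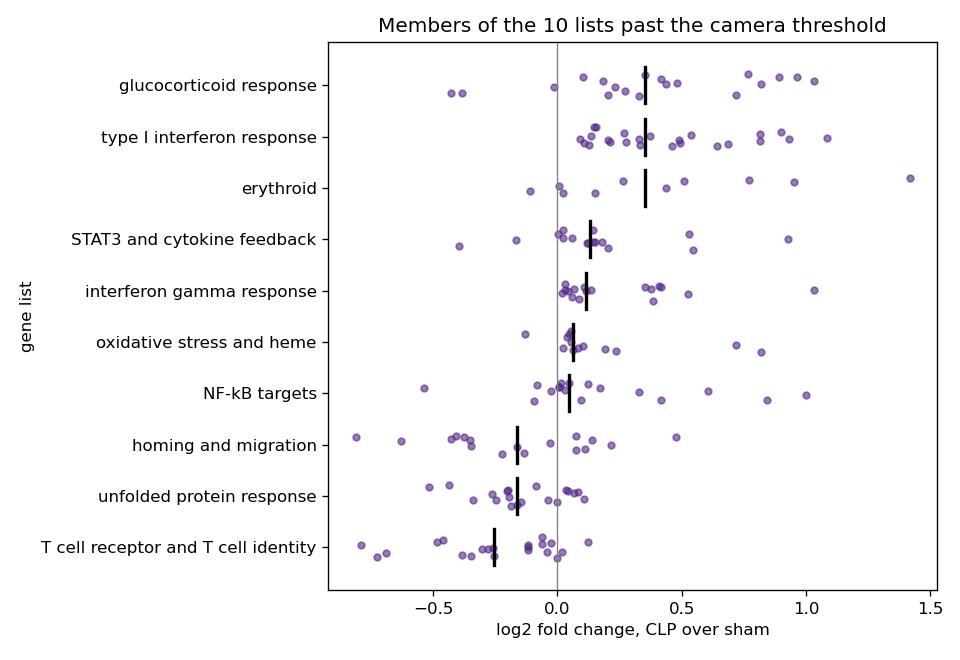
Log2 fold change (CLP over sham, x axis) of each measured member (points) of the 10 gene lists past the camera threshold (y axis), with the median of each list as a bar. The type I interferon members all lie above 0, and 19 of the 21 T cell receptor and identity members lie below it.

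NF-kB targets had a median of 0.05 over 17 members (camera adjusted p = 0.017; adjusted p = 0.486 with an estimated correlation). None passed over all genes tested, and adjusted over the list alone 4 rose, among them Tnfaip3 (A20, an inhibitor of NF-kB signalling; 1.00 ± 0.20) and Birc3 (0.61 ± 0.13), and Traf1 fell. With the 18S rRNA class as a block Tnfaip3 and Birc3 passed over all genes tested (adjusted p = 0.0293 and 0.0272). Over 27 other settings, this block among them, Tnfaip3 passed in 11 and Birc3 in 6. The STAT3 and cytokine feedback list had a median of 0.13 over 16 members (camera adjusted p = 0.017; adjusted p = 0.465 with an estimated correlation). Its member Socs3, which shuts off STAT3 signalling, rose 1.46-fold, and adjusted over the list alone Cebpb also rose (adjusted p = 0.028 over all genes with the class as a block) and Pim2 fell. Cebpb passed over all genes in 2 of those 27 settings. The immediate early and activation list did not shift as a whole (camera adjusted p = 0.643), and its members went both ways. Its members Tnfrsf9 and Tnfrsf4 (OX40), costimulatory receptors, rose by 1.92-fold and 1.90-fold, while adjusted over the list alone Egr3 (-1.07 ± 0.28) and Egr2 (-0.63 ± 0.19), transcription factors induced by the T cell receptor, fell. The other probe set of Egr3 went the opposite way, and the average of both was -0.52.

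Genes of the T cell receptor and of T cell identity were lower as a group, with a median log2 fold change of -0.25 over 21 members, 19 of them lower (camera adjusted p = 0.00014; adjusted p = 0.407 with an estimated correlation). None fell over all genes tested by its brightest probe set, and 3 fell when adjusted over the list alone: Trat1, a T cell receptor adaptor (-0.72 ± 0.16), Cd5 (-0.69 ± 0.17) and Gata3 (-0.46 ± 0.13). A dimmer probe set of Trat1 passed at -1.28 ± 0.16 (adjusted p = 0.0163). With the 18S rRNA class as a block 5 members fell over all genes tested: Thy1 (-0.79, adjusted p = 0.0144), Trat1 (0.0232), Cd5 (0.0326), Cd3g (0.0426) and Gata3 (0.043). Over 27 other settings, that block among them, Trat1 passed in 6, Thy1 and Cd5 in 3 each and Gata3 in 1, the block itself. Cd4 and Cd3e differed by -0.12 ± 0.13 and -0.12 ± 0.09 and did not pass, Cd4 running from -0.21 without sham replicate 2 to -0.02 without sham replicate 5. The homing and migration list had a median of -0.16 over 17 members (camera adjusted p = 0.017; adjusted p = 0.407 with an estimated correlation). Ccr9, the gut-homing chemokine receptor, was 1.75-fold lower, and adjusted over the list alone 5 members fell, with the integrins Itgb7, Itga6 and Itgb2 and the receptor Cxcr3. With the class as a block Itgb7 and Itgb2 passed over all genes tested (adjusted p = 0.0293 and 0.0459), and dimmer probe sets of Ccr2 and Itga4 passed without it at -0.99 ± 0.13 and -0.70 ± 0.13 (adjusted p = 0.0163 and 0.0373). Itgb7 passed in 2 of the 27 settings and Itgb2 in 1, the block itself. The unfolded protein response list had a median of -0.16 over 19 members (camera adjusted p = 0.0356; adjusted p = 0.548 with an estimated correlation), of which none passed over all genes tested or adjusted over the list alone. Among heat shock genes, Hsph1 was 1.93-fold lower and Dnaja1 fell when adjusted over the list alone (adjusted p = 0.0292 over all genes with the class as a block), and the list did not pass (camera adjusted p = 0.119). Dnaja1 passed over all genes in 3 of the 27 settings.

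The factors of T helper and regulatory T cells changed singly and not as a list (16 members, camera adjusted p = 0.582). Tbx21 fell (log2 fold change -0.93 ± 0.17, adjusted p = 0.0358 by limma). Foxp3, which defines regulatory T cells, gave 1.10 ± 0.22 (adjusted p = 0.053), Ctla4, an inhibitory receptor abundant on them, 1.44 ± 0.29 (adjusted p = 0.0513), and Nrp1, a receptor of thymus-derived regulatory T cells, -1.29 ± 0.27 (adjusted p = 0.0616). These 3 missed the threshold over all genes and passed it when adjusted over the list alone, where 3 members rose and 4 fell in all. With the 18S rRNA class of the arrays as a block their adjusted p became 0.0277, 0.028 and 0.0263. Over 27 other settings, the block among them, Foxp3 passed in 10, Ctla4 in 13 and Nrp1 in 4. Il10 was the only one of 11 measured T helper cytokines that rose (camera adjusted p = 0.355 for the list), and Il2 gave 0.52 ± 0.20 and Tnf -0.08 ± 0.11. Of 11 measured inhibitory receptors none passed over all genes tested, and adjusted over the list alone Ctla4 rose and Cd5 fell (camera adjusted p = 0.751). With the class as a block Ctla4, Cd5 and Cd160 (-0.36) passed over all genes tested, Cd160 with an adjusted p = 0.0475. Of the 27 other settings Cd160 passed in only 1, that block itself, and it ran from -0.43 to -0.13 over them. Of its 2 other probe sets 1 went the same way.

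**Figure D3:**
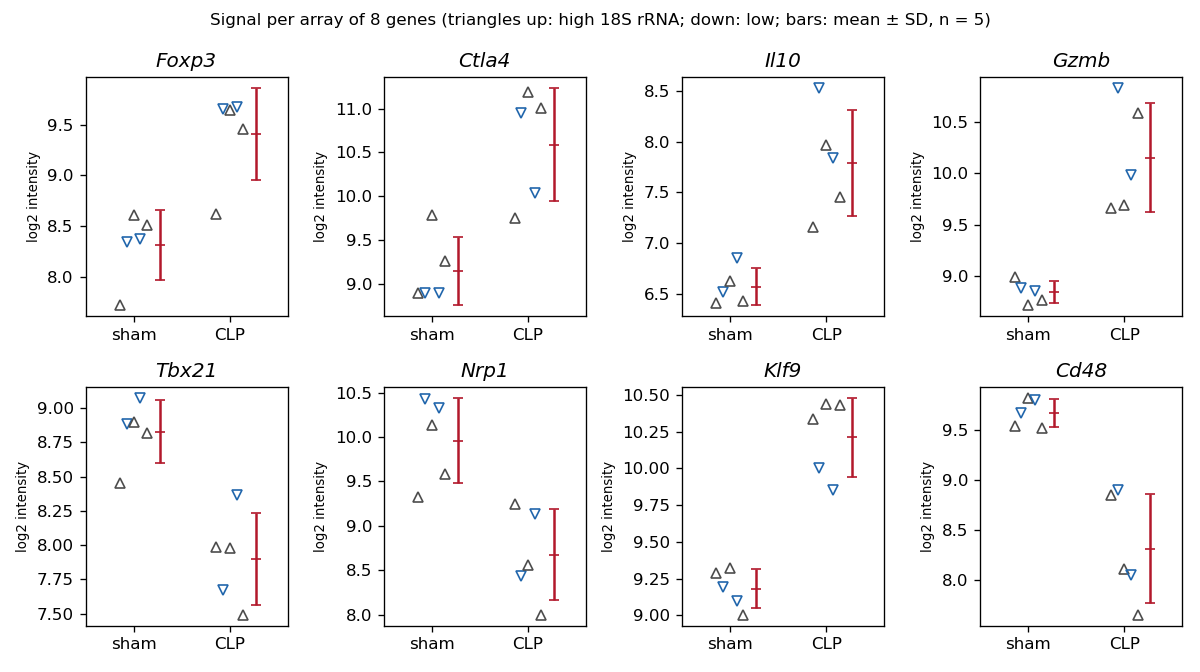
Log2 intensity (y axis) per array of 8 genes in sham and CLP mice (x axis), with triangles up for arrays of high and down for arrays of low 18S rRNA signal, and bars for the mean ± SD of the 5 mice. The CLP arrays lie above all sham arrays for Il10, Gzmb and Klf9 and below them for Tbx21, Nrp1 and Cd48; for Foxp3 CLP replicate 1 lies just above the highest sham array, and for Ctla4 just below it.

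Genes of cell death did not shift in one direction as groups at 6 h by camera, while fry's test for changes in either direction passed the anti-apoptotic list (adjusted p = 0.00855) and the p53 targets (adjusted p = 0.00126). None of 19 measured pro-apoptotic genes passed by its brightest probe set (median 0.04, camera adjusted p = 0.832). For Bcl2l11 (Bim) that probe set gave 0.55 ± 0.21 (adjusted p = 0.303, and 0.0156 with the 18S rRNA class as a block), while a dimmer one passed at 0.72 ± 0.12 (adjusted p = 0.0311). Over 27 other settings the gene Bcl2l11 passed in 2, the block among them. Of 11 anti-apoptotic genes Birc3 rose when adjusted over the list alone (camera adjusted p = 0.0982), and of 13 p53 targets Ccng1 fell when adjusted over the list alone (-0.40 ± 0.08, camera adjusted p = 0.832 for the list). With the class as a block Birc3, Cflar (-0.50) and Ccng1 passed over all genes tested (adjusted p = 0.0272, 0.0381 and 0.0341). Of the 27 settings Birc3 passed in 6 and Ccng1 in 5. No member passed over all genes tested by its brightest probe set in the lists of oxidative phosphorylation (27 measured, camera adjusted p = 0.506), glycolysis (16, 0.276), ribosomal proteins (15, 0.69), ribosome biogenesis (20, 0.349), the proteasome (21, 0.105) and the cell cycle (20, 0.144). Adjusted over the list alone, Slc16a3, a lactate transporter of the glycolysis list, rose (0.34 ± 0.09), and no member of the other 5 passed. The median, mean and test of the immediate early, p53 and oxidative phosphorylation lists differed in sign, all within 0.02 of 0.

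Markers of other cell types were read for the cells that the enrichment left. The erythroid list was higher in CLP arrays (median 0.35 over 10 members, camera adjusted p = 0.017; adjusted p = 0.548 with an estimated correlation), led by Slc4a1, the red cell anion exchanger (1.42 ± 0.57), and Alas2 (0.95 ± 0.45, and 0.49 without CLP replicate 1), and none passed over all genes tested or adjusted over the list alone. No member passed either way in the lists of B cells (17 measured, camera adjusted p = 0.144), plasma cells (7, 0.168), neutrophils (16, 0.471), dendritic cells (11, 0.144), CD8 T cells (4, 0.582) and endothelium and stroma (7, 0.476). Over all genes tested none passed among 16 markers of monocytes and macrophages (camera adjusted p = 0.69) and 7 of platelets (0.476), and 1 of 12 did in the NK and cytotoxic list (0.275). In the NK and cytotoxic list Gzmb rose, while adjusted over the list alone 5 members fell, among them Klrg1 (-0.35 ± 0.11), Klrd1 (-0.54 ± 0.17, adjusted p = 0.0359 over all genes with the class as a block) and Nkg7 (-0.24 ± 0.08). That block was the only 1 of 27 other settings in which Klrd1 passed over all genes. In the monocyte list Cd14 rose (0.72 ± 0.21) and Vcam1 fell (-1.20 ± 0.33, and -0.42 with its probe sets averaged) when adjusted over the list alone. Of the platelet list Itgb3 fell (-0.44 ± 0.12, and from -0.52 to -0.24 over 27 other settings) in the same way. The markers Cd8a, Lyz2 and S100a8 differed by 0.09 ± 0.11, -0.10 ± 0.17 and -0.82 ± 0.56 and did not pass; S100a8 ran from -0.51 without sham replicate 1 to -1.37 without CLP replicate 1, Lyz2 from -0.02 to -0.26 without the same arrays, and Cd8a from 0.03 without sham replicate 3 to 0.18 without sham replicate 1.

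No list mean per array passed after adjustment in two-sided tests. The smallest p that 5 against 5 allows is 0.00794, so over 33 lists none can pass unless several reach it together. The lack of a pass therefore does not count against a change. The type I interferon mean was 0.44 log2 units higher in CLP arrays (9.07 ± 0.13 against 8.63 ± 0.22, SD, n = 5, exact permutation p = 0.0159, adjusted p = 0.21 over 33 lists). The glucocorticoid mean was 0.39 higher (exact permutation p = 0.0238, adjusted p = 0.21) and the T cell receptor and identity mean 0.26 lower, at 10.89 ± 0.10 against 11.15 ± 0.18 (exact permutation p = 0.0317, adjusted p = 0.21). The interferon gamma mean was 0.25 higher (exact permutation p = 0.0317, adjusted p = 0.21). The dendritic cell mean was 0.06 higher (exact permutation p = 0.00794, the smallest that 5 against 5 allows, adjusted p = 0.21), and the erythroid mean 0.44 higher (exact permutation p = 0.135), or 0.29 without CLP replicate 1.

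The arrays fell into a pair of classes that cut across the surgery. The middle probe set of 18S ribosomal RNA read between 3134 and 5178 in replicates 1, 3 and 5 of both groups, and between 194.3 and 268.4 in replicates 2 and 4 of both. Malat1, a nuclear long noncoding RNA, was lower in the low class by a log2 difference of -3.27, and 4081 probe sets differed between the classes by limma. With the class as a block, 88 genes rose and 267 fell, and all 98 genes of the unblocked comparison kept their call. Their fold changes could not move, since each group holds 3 high and 2 low arrays. The block changes only the spread and the p-values. It was added after the data were seen, so genes that pass mainly with it are weaker calls. No gene passed limma's threshold within the high class (3 against 3 arrays, 1600 genes at an unadjusted p under 0.05) or within the low class (2 against 2, 913 genes). The type I interferon mean was 0.34 higher in CLP arrays within the high class and 0.59 within the low class, and the T cell receptor and identity mean was lower by values of -0.30 and -0.19. No probe set passed limma's test for a difference in the CLP effect between the classes (1032 at an unadjusted p under 0.05).

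The first principal component (37.0% of the variance) followed these classes, and the second (18.6%) was higher in CLP than in sham arrays (15.9 ± 16.1 against -15.9 ± 4.27, SD, n = 5, exact permutation p = 0.00794, adjusted p = 0.0952 over 12 array measures). The difference between 3 prime and 5 prime control probe sets of Gapdh and beta-actin averaged 3.64 ± 0.36 log2 units in CLP and 3.66 ± 0.42 in sham arrays (exact permutation p = 0.952). Some genes were called only by a probe set dimmer than the one that stands for them here. Of 63 such genes 55 fell and 8 rose, among them Ccr2, Itga4, Slamf6, Cd53, Rora and Rps24, whose brightest probe sets gave 0.07, -0.16, 0.23, 0.04, 0.05 and -0.03.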

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

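The tests of the classes' balance across surgery, of the rise that other spleen cells would need and of the slope on the 3 prime bias were chosen after the result was seen. The tests of the other explanations were set before they ran, though the classes of arrays were themselves found in the data.

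In 384 groups of 5 values tested for a mouse far from the rest, 24 stood out, where chance gives about 19.2. The numbers in this paragraph are the gap to the nearest mouse as a share of the group's range. CLP replicate 1 stood apart in 7 of them: high in S100a8 (0.712), Lyz2 (0.765), the neutrophil list mean (0.726) and Hsph1 (0.804), and low in Foxp3 (0.797), Tnfrsf4 (0.808) and the platelet list mean (0.787). Its S100a8 log2 signal was 12.5 against 9.40 to 10.3 in the other CLP mice, and its Foxp3 signal 8.62 against 9.46 to 9.67. Sham replicate 1 was high in P2ry14 (0.797), Fcgr3 (0.761) and the neutrophil list mean (0.784) and low in the oxidative phosphorylation mean (0.808). Sham replicate 5 was high in Fkbp5 (0.789), Oasl1 (0.824), Fscn1 (0.735) and Psma6 (0.756) and low in Il2 (0.77) and Wdr12 (0.738). CLP replicate 4 was high in Fscn1 (0.711) and Gp9 (0.731) and low in Ndufa8 (0.779) and Psmb2 (0.761). CLP replicate 2 was high in Mpo (0.722) and Sqstm1 (0.804), and CLP replicate 3 low in Klrg1 (0.717).

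The genes called between CLP and sham mice were set against chance and technical causes. Of 100 splits of the 10 arrays into 5 and 5, 2 called at least 98 genes, the real split included, which is fewer than the 5 fixed as the limit for chance; the other called 165 and put 5 of the 6 arrays of high 18S signal on one side. With the class as a block, 1 of 60 splits that keep the classes balanced, the real one, called as many as its 355 genes, and the highest other called 1. For the genes that fell, a loss of CD4 T cells was weighed as the cause of the whole median fall of -0.755. The median of the T cell receptor and identity list was -0.253 (bootstrap 95% interval -0.347 to -0.0628), smaller than 1 part in 2 of that fall. Among other cell types the highest list median was 0.352 (upper bound 0.772), where such a loss would need a rise of 2.36. These bounds come from resampling genes and hold no spread between mice. The values argue against a loss large enough to give the whole fall. That fall is the median of genes chosen for falling, and the T cell list itself was lower, so a smaller loss stays open. A loss of other cells from the CLP samples was not tested. With the monocyte and macrophage mean as a covariate 9 genes rose and 13 fell, and with the B cell mean 57 and 135. The monocyte and macrophage list mean differed by -0.125 between CLP and sham arrays (exact permutation p = 0.437). With the 3 prime bias as a covariate the median fall kept 1.00 of its size, which decides nothing since the groups are balanced in it. The slope on it times the group difference gave a median of -0.000582 (bootstrap 95% interval -0.0918 to 0.0227). This restates the covariate fit and is small because the groups are balanced, so it is no separate evidence. The values show only that the groups hardly differ in this measure of the bias. Of 70 other probe sets of the genes that fell, 80.0% were lower too (exact 95% interval 68.7% to 88.6%, taking probe sets as independent). In 24 of 34 genes most of theirs were lower (exact 95% interval 52.5% to 84.9%). This argues against single faulty probe sets for these genes as a set, not for each gene. With probe sets averaged, 63 of the 98 genes that rose or fell kept their call. A further 55 genes fell by a dimmer probe set alone. A change within the T cells stays a hypothesis.

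The classes of arrays by 18S signal were not set by the surgery, since 2 of the 4 low arrays were CLP. The 3 prime bias cannot be told apart from them: the Gapdh difference was lower in the low class by a log2 value of -1.15 (exact permutation p = 0.00476), while that of beta-actin differed by -0.0119 (exact permutation p = 0.967). Other cell types also stay open, as the largest class difference of their list means was -0.437 for neutrophils and its spread reaches past 0.5; CLP replicate 1 and sham replicate 1 carry it, and it is -0.239 without the former. Amplification or hybridisation on different days was not tested, since the labels name no batch.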

How the results depend on the processing

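The block by rRNA class, the fits within classes, the unscaled values and list means without single arrays were added after the data were seen. The counts of 26 genes that rose and 72 that fell stayed within 1.5 times under quantile normalization (37 and 64, so 36.6% rose where 26.5% did), centring, the 60th percentile filter, both other floors, log2(value + 16), trended and robust variances, averaged probe sets and unscaled values. Similar counts need not be the same genes: with averaged probe sets 63 of the 98 kept their call. With no filter 0 rose and 1 fell (1816 genes at an unadjusted p under 0.05), and with a minimum fold of 1.2 in limma's treat 0 and 0 (339 at an unadjusted p under 0.05). Array weights gave 80 and 167, the B cell covariate 57 and 135, the monocyte and macrophage covariate 9 and 13, the 3 prime bias covariate 54 and 154, and the rRNA class as a block 88 and 267. Only the high class gave 0 and 0, as did only the low class, with fewer arrays. Leaving out 1 array gave from 0 (without sham replicate 3) to 69 (without CLP replicate 1) genes that rose and from 2 to 179 that fell. The causes were not tested. The smaller number of arrays alone does not set these counts. Leaving out 1 array also raised them, to 69 and 179 without CLP replicate 1 and to 39 and 91 without CLP replicate 4.

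The labels do not say that a replicate number marks a shared litter, batch or day, and the numbers were not treated as pairs. With the replicate block 44 genes rose and 75 fell, and of the 98 genes 63 kept their call. Of the 24 largest rises and falls 3 no longer passed with it. Same-numbered arrays correlated in their deviations from the group means at 0.18, 0.58, 0.38, 0.18 and 0.06, of which 4 exceed 0.1 where all 5 were required, and 3 of 10 arrays correlated best with their own number. The 18S class follows the number in both groups, so shared handling stays possible.

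The count of 10 lists past the threshold became 0 with an estimated correlation, 1 with fry and 5 in only the low class; leaving out 1 array gave 6 (without sham replicate 3) to 12 lists. The type I interferon, interferon gamma and glucocorticoid lists passed in all 29 refits with the preset correlation, where the highest adjusted p were 4.87e-07, 0.00429 and 0.000103. All these refits kept the preset, so they do not test it. The T cell receptor and identity list passed in 28 of them, homing in 26, NF-kB and STAT3 in 27 each, erythroid in 24, oxidative stress in 21 and the unfolded protein response in 20. No list mean per array passed after adjustment under quantile normalization or centring, where the same limit of the permutation test holds. Signal near the floor limits what can be seen of dim genes such as Il10, Tnfsf11 and Mcoln3.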

Other observations

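The prediction for the regulatory T cell markers was written before their values were seen, while the pattern behind it was noticed in the data.

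Single genes outside the fixed lists also passed. Themis, which tunes T cell receptor signalling, was lower by a log2 fold change of -0.81 ± 0.13 (SE, limma adjusted p = 0.0236), and Tnfsf14 (LIGHT), a costimulatory TNF-family ligand, by -0.80 ± 0.12 (adjusted p = 0.0225). S100a4, a calcium-binding protein of memory T cells, gave -0.76 ± 0.14 (adjusted p = 0.0433). Lxn, a carboxypeptidase inhibitor, had the lowest adjusted p of all genes (0.00484) at -0.94 ± 0.08. Etv6, a transcriptional repressor, rose 1.73-fold. These genes were chosen after their values were seen.

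Higher Foxp3, Ctla4 and Il10 in CLP arrays raised the hypothesis of a larger share of regulatory T cells. Of 11 further markers fixed for this test 9 were measured, and their median log2 fold change was -0.0696. Its bootstrap 95% interval, from resampling markers and not mice, was -0.353 to 0.210. The limit set beforehand for a larger share was 0.548, which is 1 part in 2 of the Foxp3 change of 1.10. Gpr83 and Izumo1r (folate receptor 4), both abundant on regulatory T cells, gave -0.43 ± 0.22 and -0.35 ± 0.22, while Ecm1 gave 0.28 ± 0.13 and Swap70 0.21 ± 0.14. Other markers had been seen earlier and were kept out of the test. Of these Nrp1 gave -1.29 ± 0.27, Ikzf2 (Helios) -0.29 ± 0.14 and Il2ra (CD25) -0.10 ± 0.16. Itgae gave 0.05 ± 0.12 and Tnfrsf18 (GITR) 0.63 ± 0.21. The markers thus did not rise together with Foxp3, and the limit was not reached. Some of them are also made by other T cells and would rise less than Foxp3 with a larger share, so the test cannot exclude one. A change of Foxp3, Ctla4 and Il10 within activated cells also stays open as a hypothesis.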
